A study of Homo sapiens with 2 samples.

How the data were processed

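Sorted PAX7-Venus cells of the NCRM1 induced pluripotent stem cell line were profiled by inDrops in 2 libraries from independent experiments, per the labels. The cells were dissociated with collagenase and trypsin and sorted for Venus by flow cytometry before capture, per the labels' protocols, and the settings of that sort bear on every share of cells given here. The submitters' processing notes name Trimmomatic, Bowtie 1.2.2 and the GRCh38.p12 build without saying what each did. The gene annotation, the barcode filter, the UMI collapsing and the settings of the authors' clustering are not given in the sources used here.

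The authors deposited 1 matrix of 1427 cells by 20086 genes and a table of cells with total counts, genes per cell and cluster. The deposited matrix holds the natural log of 1 plus the UMI count, with no scaling for depth: after the log was undone, 100% of the non-zero values were whole within 0.001, and the largest distance from a whole number was 0.000124. Per cell, the recovered counts summed to between 99.2% and, at the median, 99.9% of the total UMI count that the authors give in the deposited cell table. Raw counts could thus be used, and the count tests planned before the data were examined were kept. All lists, tests, alternatives and the rule for named genes were also fixed before the data were examined unless stated otherwise. Every gene in the matrix had a UMI in at least 3 cells, and the smallest cell total was 2511, so the planned filters on low totals removed no cell. A set of 16 X-inactivation and Y-linked genes was left out on loading, which left 20070 genes. Library identity came from the start of each cell's barcode in the cell table.

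Cell groups were the authors' 4 clusters. A name needed at least 3 detected markers of a list fixed beforehand and 10 leading genes (by log2 fold over the mean of the other clusters) with more markers of that list than of any other. Marker lists covered progenitor, committed myoblast, differentiated myocyte, cycling, neural progenitor, neuron, neural crest or Schwann, mesenchymal, chondrogenic or tendon, smooth muscle or pericyte, endothelial, epithelial, pluripotent and blood cells. Clusters 1 and 3 had 6 and 5 such markers. Clusters 0 and 2 had 1, mesenchymal and neural crest, and were left unnamed by a judgement, made after these counts were seen, that 1 marker is too few. They were compared by number, with cluster 0 in the place of the progenitor class of the plan.

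Counts were summed per library and cluster, giving 8 sums, and fitted together in edgeR 4.0.16 with R 4.3.3 (TMM factors 0.886 to 1.11, filterByExpr, glmQLFit and glmQLFTest, two-sided, Benjamini-Hochberg threshold 0.05 over 9654 genes). The fit held a term for library, because each library gave cells to every cluster and pairs the sums by origin; 3 residual degrees of freedom remained and the biological coefficient of variation was 6.49%. Standard errors are the log2 fold divided by the square root of F. With n = 2, the p-values rest on the spread shared across genes. CPM values are TMM-scaled except where libraries are compared as a whole. On simulated data with known changes for cluster 2 against cluster 0 (9083 genes), 90.8% of 4-fold, 59.4% of 2-fold and 18.2% of 1.5-fold changes were found. The shares were 88.9%, 43.5% and 21.3% for cluster 3 (9081 genes) and 85.5%, 68.8% and 32.3% for cluster 1 (9060 genes). In the simulated data few genes changed and all clusters otherwise had the same mean profile, with no library effect and no clustering step. These shares are thus a guide only and need not hold for the comparisons made here.

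Gene lists were tested with camera (limma 3.58.1) on log2 CPM of the same sums with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The version with an estimated correlation rests on 3 residual degrees of freedom; with it only the S phase and G2M lists in cluster 1 passed. The lists were Notch, cell cycle inhibitors, S phase, G2M, sarcomere and Z disc, excitation contraction coupling and neuromuscular junction, fusion and adhesion, basement membrane and matrix, growth factor receptors, imprinted growth genes, premyogenic transcription factors, satellite cell surface, fetal and embryonic stage, HOX, glycolysis, oxidative phosphorylation, dissociation stress, WNT and BMP. Genes named in the text are PAX7, PAX3, MYF5, MYOD1 and MYOG, the 10 largest changes each way among genes past the threshold with the same sign in both libraries and at least 50 CPM in the higher cluster of both (markers, ribosomal and mitochondrial genes left out), and up to 4 members of each list; marker genes, and other list members given as examples, were picked after their values were seen. A gene with 0 UMIs in a cluster is given as a bound against a floor of 3 UMIs over that cluster, and one with 1 to 3 UMIs as a ratio with its exact counting interval. Genes with stretches of similar sequence, such as members of the HOX and actin families, may carry added uncertainty, since the counting of shared reads is not given in the sources used here. Positions of genes are from GENCODE release 29 on GRCh38.

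Shares of cells carry exact binomial 95% intervals, which cover counting error only, and a count of 0 is given with the limit of 3 counts. Detection was compared after each cell was thinned to 2500 UMIs, with 5000 as an alternative. Co-detection is an odds ratio with an exact conditional interval per library. Doublets were called per library with the Scrublet method of scanpy 1.11.5 (expected rate 0.06), which marked 12 of 610 and 15 of 817 cells; they were kept and left out as an alternative. Alternatives were RLE factors, DESeq2 1.42.0, no filter on low counts, no library block, only the compared clusters, thinned cells, a count split (each UMI sent at random to 1 of 2 parts, Leiden clusters from 1 part, tests on the other), rebuilt clusters, and each library alone. Each rebuilt cluster, those of the count split included, took the number of the authors' cluster that held most of its cells. The authors' clusters were not made from 1 part alone, so the parts of the count split were not fully separate. Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1 did the other computing.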

Results

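Single-cell transcriptomes were measured by inDrops, a droplet method in which each captured mRNA receives a unique molecular identifier (UMI). The cells came from NCRM1, a human induced pluripotent stem cell line. In this line the fluorescent protein Venus reports expression of PAX7, a transcription factor of skeletal muscle progenitors and satellite cells. Cells with Venus signal were sorted on day 27 of differentiation in 2 independent experiments, which gave 2 libraries of a single group (n = 2). Replicate 1 held 610 cells and 4686216 UMIs, with a median of 7459 UMIs per cell. Replicate 2 held 817 cells and 6863149 UMIs, with a median of 8341. The authors' cell table placed every cell in 1 of 4 clusters, numbered 0 to 3. All comparisons were between these clusters within the same 2 libraries, since the series has no second group.

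The first question was which cells the sorted population held. Cluster 0 made up 60.1% ± 2.71 of the cells (mean ± SD, n = 2), cluster 1 18.3% ± 0.896, cluster 2 13.1% ± 2.36 and cluster 3 8.47% ± 0.547. The share of cluster 0 was 62.0% in replicate 1 (378 of 610 cells, exact 95% interval 58.0 to 65.8) and 58.1% in replicate 2 (475 of 817 cells, 54.7 to 61.5), intervals that cover counting error only. Cluster 1 was called cycling-like, because 6 of its 10 leading genes were cycling markers, among them TOP2A, CENPF, UBE2C and CDK1. Cluster 3 was called differentiated myocyte-like, because 5 of its 10 leading genes were markers of that class: the skeletal actin ACTA1, titin (TTN), the myosin light chains MYL1 and MYLPF, and embryonic myosin heavy chain (MYH3). Clusters 0 and 2 each had 1 marker among their 10 leading genes, mesenchymal in cluster 0 and neural crest in cluster 2, and none of a myogenic list. A single marker was judged too little for a name, so both stay unnamed. The leading genes of cluster 0 included OGN, MATN2, SFRP2 and its 1 marker POSTN, which few cells carried: 127 and 586 CPM in 52 cells of the cluster that rebuilt clusters set apart, and 2431 and 4261 CPM in a further 6, against 1.23 and 2.85 in the cluster without both groups. Those of cluster 2 included NGFR, a marker on the neural crest list, together with the carboxypeptidase M gene, SOX8 and EDN3.

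Markers of other lineages differed widely between lists. No cell had UMIs of 3 or more markers from the neural crest, endothelial, epithelial or blood lists (0 of 610 and 0 of 817 cells). By counting error alone this allows up to 0.492% and 0.367% of cells with 3 such markers, which is no bound on cells of these types. Only 5 of 10 neural crest, 5 of 8 endothelial, 6 of 8 epithelial and 5 of 8 blood markers were in the matrix, and a cell can express a marker without a captured UMI. The pluripotent list reached 3 markers in 0 and 1 cells of replicates 1 and 2, the neural progenitor list in 1 and 3 cells, and the chondrogenic or tendon list in 6 and 3 cells. Neuron markers reached that number in 46 and 117 cells, and of 5 measured between clusters 3 and 0, DCX, NEFM and NEFL were higher in cluster 3 and TUBB3 and GAP43 lower. At least 3 mesenchymal markers had UMIs in 95.4% of the cells of replicate 1 and 96.5% of those of replicate 2, and the smooth muscle or pericyte list reached 3 in 48.7% and 48.0%. In the myocyte-like cluster 3 alone these shares were still 57.4% and 62.1%, and 13.0% and 10.6%. Such abundant genes can reach 3 markers through free RNA, so the shares do not count mesenchymal cells. Markers of the progenitor, committed myoblast, differentiated myocyte and cycling lists reached 3 in 42.3%, 37.2%, 36.1% and 18.4% of the cells of replicate 1 and in 54.2%, 42.6%, 41.0% and 20.4% of those of replicate 2, unthinned. No cluster was named as a non-myogenic class, so the planned comparison of such a class was not made.

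The regulator PAX7 itself (chromosome 1, 18631006 to 18748866, GRCh38) was read in each cluster, since the sort rests on it. PAX7 stood at 133 ± 25.4 CPM (UMIs of a gene over all UMIs, scaled as in edgeR) in cluster 0, 118 ± 22.4 in cluster 1, 76.0 ± 9.83 in cluster 2 and 10.5 ± 4.19 in cluster 3 (mean ± SD, n = 2). After every cell was thinned to 2500 UMIs, which left out no cell, 21.6% of the cells of replicate 1 (132 of 610, exact 95% interval 18.4 to 25.1) and 25.6% of those of replicate 2 (209 of 817, 22.6 to 28.7) had a PAX7 UMI, a mean of 23.6% ± 2.79. By cluster the thinned shares were 28.1% ± 4.93, 25.4% ± 3.25, 14.8% ± 3.36 and 2.61% ± 1.55 in clusters 0 to 3. Cluster 3 had the lowest share, the planned reference level, with median depths of 8112.5 and 8534 UMIs per cell in replicates 1 and 2 against 7158 and 8237 in cluster 0. Unthinned, 48.1% ± 9.07 of all cells and 6.73% ± 0.952 of cluster 3 had a PAX7 UMI, so the absolute share was set by depth.

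**Figure D1:**
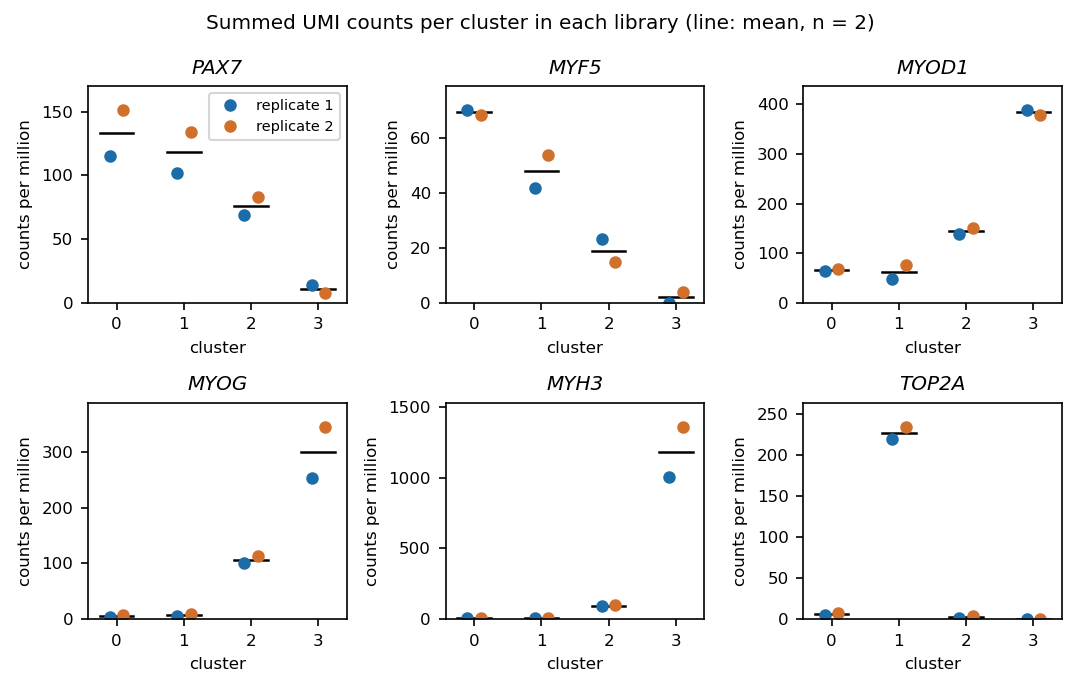
TMM-scaled CPM of PAX7, MYF5, MYOD1, MYOG, MYH3 and TOP2A (vertical axes) in clusters 0 to 3 (horizontal axes); points are the 2 libraries and lines their mean. PAX7 goes from 133 in cluster 0 to 10.5 in cluster 3, MYOG from 5.77 to 299.6, and TOP2A is at 227 in cluster 1.

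Whether PAX7 was found in the same cells as other myogenic regulators was asked across all cells, without using clusters. At 2500 UMIs per cell, PAX7 and MYF5, an early myogenic determination factor, were detected in the same cell more often than independent detection gives, with odds ratios of 1.94 (exact 95% interval 1.02 to 3.61) in replicate 1 and 1.89 (1.10 to 3.19) in replicate 2. These limits lie close to 1: at 5000 UMIs the PAX7 and MYF5 odds ratios were 1.57 (0.937 to 2.62) and 1.42 (0.911 to 2.23), and without called doublets that of replicate 1 was 1.90 (0.981 to 3.57). Unthinned, with depth not matched between cells, they were 3.37 (2.15 to 5.35) and 2.19 (1.49 to 3.25). PAX7 and MYOD1, the determination factor of committed myoblasts, had an odds ratio of 0.512 (0.259 to 0.946) in replicate 1 and 0.668 (0.428 to 1.02) in replicate 2. PAX7 and MYOG, which drives terminal differentiation, had 0.422 (0.107 to 1.22) and 0.280 (0.107 to 0.624). At 5000 UMIs MYOD1 had 0.664 (0.422 to 1.03) and 0.597 (0.422 to 0.841), and MYOG had 0.341 (0.135 to 0.759) and 0.292 (0.165 to 0.499). For PAX3, the paralog of PAX7 in the embryonic limb and somite, the odds ratios of 1.56 (0.257 to 6.97) and 0.787 (0.258 to 2.04) had wide intervals on both sides of 1. Within cluster 0 alone, the PAX7 and MYF5 odds ratio was 2.29 (1.12 to 4.58) in replicate 1 and 1.24 (0.643 to 2.33) in replicate 2. For MYOD1 it was 0.742 (0.301 to 1.65) and 0.917 (0.5004 to 1.63) there, and for MYOG 9.40 (0.744 to 499) and 1.24 (0.263 to 4.98), so the values below 1 for MYOD1 and MYOG across all cells were not resolved inside the cluster.

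**Figure D2:**
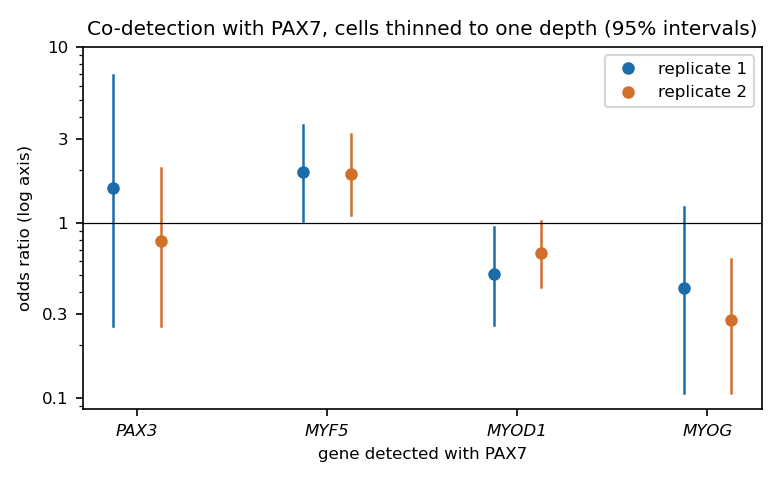
Odds ratio of detecting PAX7 and a second gene in the same cell (vertical, log axis) for PAX3, MYF5, MYOD1 and MYOG (horizontal), per library after thinning; bars are exact 95% intervals of counting error. MYF5 lies at 1.94 and 1.89 and MYOG lies at 0.422 and 0.280.

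Cluster 2 was compared with cluster 0, the largest cluster. MYOG (chromosome 1, 203083132 to 203086036) was 18.6-fold higher in cluster 2, at 107 ± 9.94 against 5.77 ± 3.08 CPM, and MYOD1 (chromosome 11, 17719568 to 17722131) was higher by 1.23 ± 0.16 on the log2 scale (± after a log2 fold is its SE, and after CPM the SD over n = 2). PAX7 fell by 0.73 ± 0.17 and MYF5 (chromosome 12, 80716912 to 80719673) fell by 1.86 ± 0.28. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment these 4 genes had adjusted p = 1.3e-59, 4.5e-13, 0.00035 and 1.2e-09. PAX3 (chromosome 2, 222199888 to 222298996) had a log2 fold of -0.68 ± 0.50 that did not pass by edgeR (adjusted p = 0.44). All 10 committed myoblast markers rose, among them the fusion proteins myomixer (MYMX, 5.07 ± 0.22) and myomaker (MYMK, 4.45 ± 0.68). Of 10 myocyte markers 8 rose, with MYLPF at 4.38 ± 0.13 and MYH3 at 3.50 ± 0.23. Of 9 measured progenitor markers 3 rose (CDH15, ERBB3 and FGFR4) and 4 fell (MYF5, SPRY1, HEY1 and PAX7). Of 8 measured mesenchymal markers 7 fell and none rose (8 adjusted over the list alone), among them COL1A1 and COL3A1, and of 5 smooth muscle or pericyte markers 4 fell (4 adjusted over the list alone), among them TAGLN and ACTA2. Neuron markers went both ways, with 3 of 5 measured higher and 1 lower (3 and 1 adjusted over the list alone).

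Among genes outside the marker lists and at 50 CPM or more in the higher cluster, the largest rises in cluster 2 were those of GADD45G, a stress-inducible growth arrest gene (4.32 ± 0.34), and KREMEN2, a receptor for the WNT antagonist DKK1 (4.15 ± 0.26). Next came the transcription factor SOX8 (4.06 ± 0.20), PGBD5 (3.77 ± 0.26), AC009041.2 (3.73 ± 0.27) and FITM1, which promotes lipid droplet formation (3.68 ± 0.23). Brain-type creatine kinase (CKB, 3.68 ± 0.11), the ISG15 protease USP18 (3.65 ± 0.17), AC020909.2 (3.64 ± 0.27) and the delta subunit of the muscle acetylcholine receptor (CHRND, 3.54 ± 0.20) followed. The largest falls were those of the cytochrome P450 CYP1B1 (-4.45 ± 0.44), the secreted WNT modulator SFRP2 (-4.08 ± 0.27), FIBIN (-3.75 ± 0.27), and the small leucine-rich proteoglycan OGN (-3.58 ± 0.22). They were followed by the chemokine CXCL12 (-2.93 ± 0.22), RGCC (-2.90 ± 0.20), ADAMTS16 (-2.79 ± 0.28), the matrix protein MATN2 (-2.77 ± 0.20), LRRC3B (-2.63 ± 0.31) and the endothelin receptor EDNRA (-2.59 ± 0.31). All 20 of these genes also passed when separate parts of the UMIs made the clusters and were tested. They had been picked with all UMIs, the tested part included, so their passing is no independent check.

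Of 23 measured sarcomere and Z disc genes, 15 rose and 1 fell in cluster 2 (15 and 1 adjusted over the list alone), with a median log2 fold of 1.16. The cardiac and fetal actin ACTC1 rose by 1.83 ± 0.08 and desmin (DES) by 1.16 ± 0.14, while the tropomyosin TPM1 fell by 1.05 ± 0.13. The myosin chaperone UNC45B rested on 13 UMIs in cluster 2 and 3 in cluster 0, a ratio of 19.7 (counting interval 5.42 to 108.0). The list passed camera with its preset correlation (adjusted p = 4.1e-08) but not with an estimated correlation (adjusted p = 0.24). Of 14 excitation contraction coupling and neuromuscular junction genes 6 rose (6 adjusted over the list alone), among them STAC3 (2.53 ± 0.21) and RAPSN (1.03 ± 0.14), with camera adjusted p = 0.0005 (adjusted p = 0.24 with an estimated correlation). Of 36 oxidative phosphorylation genes 4 rose and the rest did not pass (4 adjusted over the list alone). COX7A2 was the largest of them at 0.45 ± 0.10, and camera gave adjusted p = 0.012 (adjusted p = 0.44 with an estimated correlation, 0.0805 without the library block and 0.0700 with fry).

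Of 22 basement membrane and matrix genes 12 fell and 3 rose (13 and 5 adjusted over the list alone), with fibronectin (FN1) at -1.77 ± 0.11 and COL6A3 at -1.62 ± 0.12. The proteoglycan HSPG2 and dystroglycan (DAG1) were among the rises. Camera gave adjusted p = 0.025 (adjusted p = 0.25 with an estimated correlation). Of 9 BMP pathway genes 3 fell (GREM1, FST and BMP4) and BMP7 rose (3 and 1 adjusted over the list alone), with camera adjusted p = 0.012 (adjusted p = 0.25 with an estimated correlation). Of 16 growth factor receptors 6 fell (6 adjusted over the list alone), among them TGFBR2 at -1.47 ± 0.24 and IGF1R at -0.91 ± 0.22, with camera adjusted p = 0.047 (adjusted p = 0.25 with an estimated correlation). Of 14 measured HOX genes 2 fell, HOXD1 and HOXD9 (2 adjusted over the list alone), with camera adjusted p = 0.0090 (adjusted p = 0.25 with an estimated correlation). The cell cycle lists passed camera as lower, while hardly any member passed and neither list passed fry. Of 52 G2M genes only TMPO fell (1 adjusted over the list alone; camera adjusted p = 0.0030, adjusted p = 0.36 with an estimated correlation and 0.141 with fry), with a median of -0.45, or -0.27 with 6 genes without UMIs set at their bound. Of 38 S phase genes the only one past the test was SLBP, which rose (0 adjusted over the list alone), against a list median of -0.24 and camera adjusted p = 0.0499 (adjusted p = 0.25 with an estimated correlation, 0.0569 with RLE factors, 0.0694 without the library block and 0.0604 with fry).

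The remaining lists did not pass camera between clusters 2 and 0, though single members did. Of 10 Notch pathway genes 5 rose and 2 fell (5 and 2 adjusted over the list alone): the ligand DLL1 rose by 3.89 ± 0.45, and the receptor NOTCH1 by 1.63 ± 0.23. The target HEYL rose by 1.30 ± 0.20, while NOTCH2 fell by 1.08 ± 0.17 (camera adjusted p = 0.099). Of 13 cell cycle inhibitors 4 rose and 2 fell (4 and 2 alone), with the antiproliferative BTG2 at 1.61 ± 0.21, and the median was 0.00 against a mean of 0.38 (camera adjusted p = 0.81). Of 13 WNT genes 1 rose and 3 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.0898). Of 13 fusion and adhesion genes 5 rose and 4 fell (5 and 6; 0.89), and of 12 imprinted genes 1 and 3 (1 and 3; 0.20). Of 10 satellite cell surface genes 3 rose and 2 fell (3 and 3; 0.89), with CD82 rising by 1.81 ± 0.20 and CXCR4 falling by 0.81 ± 0.21. Of 14 premyogenic factors 3 rose and 3 fell (3 and 5; 0.81), with a median of 0.15 against a mean of -0.00. Of 10 fetal and embryonic stage genes 3 fell (3; 0.31), and of 19 glycolysis genes 2 rose and 3 fell (2 and 3; 0.22). Of 17 dissociation stress genes 4 rose and 6 fell (4 and 10; 0.31), but FOS and HSPA1A changed direction with the library. FOS had a log2 fold of 1.08 in replicate 1 alone against -2.77 ± 0.51 in the fit, and HSPA1A had -0.20 against 1.12 ± 0.23.

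In all, 726 genes were higher and 662 lower in cluster 2 among 9654 tested (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 385 and 380 of them by over 2-fold, and 1380 of the 1388 had the same sign in both libraries. Here and in the comparisons below, genes whose sign differs between libraries rarely pass a test on both, so shared signs are no separate check. The authors' clusters were made from the same counts that were tested, so p-values describe groups chosen from these data; 835 of 6581 genes passed when separate parts of the UMIs made the clusters and were tested. No balance between rises and falls is read from this, since 678 were higher and 741 lower with RLE factors and 524 and 782 with no filter on low counts. The count was 694 without the library block, 615 with cells thinned to 2500 UMIs and 584 with DESeq2.

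Cluster 3, the differentiated myocyte-like cells, was then compared with cluster 0. MYOG was 54.9-fold higher, at 299.6 ± 64.7 CPM, and MYOD1 was 6.47-fold higher, at 384 ± 6.63 CPM. PAX7 fell by 3.56 ± 0.32 on the log2 scale, and MYF5, with 2 UMIs in cluster 3 against 462 in cluster 0, was lower by a ratio of 35.2 (counting interval 9.70 to 292). PAX3 had 1 UMI in cluster 3 against 90 (ratio 13.7, 2.40 to 548). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, these 5 genes had adjusted p = 9.4e-148, 2.7e-77, 1.5e-26, 9.2e-18 and 0.0024. All 10 committed myoblast and all 10 myocyte markers rose, with muscle creatine kinase (CKM) at 8.30 ± 0.53 and ACTA1 at 7.95 ± 0.14. The cluster was named by myocyte markers, ACTA1 among them, so the rise of that list follows from the name. All 8 measured mesenchymal markers fell, with COL1A1 at -4.24 ± 0.10 and COL3A1 at -4.21 ± 0.12, and of 9 progenitor markers 6 fell while ERBB3 and CDH15 rose. Smooth muscle or pericyte markers were mostly lower too, with 4 of 5 lower and 1 higher (4 and 1 adjusted over the list alone).

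Among the 10 largest rises outside the markers, by the same limit of 50 CPM, CASQ2, a calcium-binding protein of the sarcoplasmic reticulum, had 117 UMIs in cluster 3 and 0 in cluster 0, at least 256-fold higher against a floor of 3 UMIs over the cluster. UNC45B had 289 UMIs against 3 (ratio 631, counting interval 214 to 3079), the connexin GJD4 121 against 1 (793, 139.7 to 31579) and the histone methyltransferase SMYD1 95 against 3 (208, 68.9 to 1024). The small heat shock protein HSPB3 rose by 8.72 ± 0.33, myosin-binding protein H (MYBPH) by 7.93 ± 0.30, and the muscle LIM protein CSRP3 by 7.77 ± 0.35. Rises in the calcium pump ATP2A1 by 7.62 ± 0.39, C1orf105 by 7.55 ± 0.41 and hemojuvelin (HJV) by 7.52 ± 0.40 followed. Among the falls, OGN had 2 UMIs in cluster 3 against 1593 (ratio 122, 33.6 to 1004), MATN2 2 against 1407 (107, 29.7 to 887), the transcription factor EBF3 1 against 881 (134, 24.1 to 5315) and CXCL12 3 against 1252 (63.7, 21.7 to 309). SFRP2 (3 against 1166 UMIs), C1QTNF3 (2 against 644) and DLC1 (2 against 496) were also near the limit of counting. Pleiotrophin (PTN) fell by 5.67 ± 0.28, ISLR by 5.12 ± 0.35 and versican (VCAN) by 5.04 ± 0.28.

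All 23 measured sarcomere and Z disc genes rose in cluster 3 (23 adjusted over the list alone), with a median log2 fold of 4.30, and of 14 excitation contraction coupling and neuromuscular junction genes 13 rose (13 adjusted over the list alone), with the acetylcholine receptor subunit CHRND at 5.12 ± 0.18 and a list median of 3.17. Camera gave adjusted p = 9.5e-20 and 1.4e-10 for these lists (adjusted p = 0.0586 for each with an estimated correlation). Of 36 oxidative phosphorylation genes 24 rose and 0 fell (24 and 0 adjusted over the list alone). COX6A2, the muscle isoform of a cytochrome c oxidase subunit, had 43 UMIs against 1 (ratio 282, counting interval 48.0 to 11387), while the next, ATP5MC3, rose by 0.94 ± 0.11, and camera gave adjusted p = 5.4e-06 (adjusted p = 0.24 with an estimated correlation). Of 22 basement membrane and matrix genes 14 fell and 3 rose (14 and 3 adjusted over the list alone), with COL6A3 at -4.66 ± 0.21 and FN1 at -4.40 ± 0.18, and with DAG1, LAMA5 and NID1 the rises (camera adjusted p = 0.00024, adjusted p = 0.20 with an estimated correlation).

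Of 13 WNT pathway genes 7 fell and 1 rose in cluster 3 (7 and 1 adjusted over the list alone). The receptor FZD4 fell by 4.43 ± 0.36 and SFRP1 by 2.87 ± 0.20, while WNT10A rose by 4.32 ± 0.81 (camera adjusted p = 0.0026, adjusted p = 0.24 with an estimated correlation). Of 9 BMP pathway genes 5 fell and 1 rose (6 and 1 adjusted over the list alone), with BMP4 at 0 UMIs against 275, at least 14.0-fold lower (camera adjusted p = 0.014, adjusted p = 0.24 with an estimated correlation). Of 14 HOX genes 8 fell and 1 rose (10 and 1 adjusted over the list alone). HOXC5 had 0 UMIs against 165, at least 8.39-fold lower, HOXC6 fell by 1.73 ± 0.32 and HOXD8 rose by 1.31 ± 0.28 (camera adjusted p = 0.0061, adjusted p = 0.24 with an estimated correlation). Of 10 satellite cell surface genes 7 fell and 2 rose (7 and 2 adjusted over the list alone), with CXCR4 at 3 UMIs against 598 and CD82 and NCAM1 the rises (camera adjusted p = 0.033, adjusted p = 0.24 with an estimated correlation, and 0.0648 with clusters rebuilt without list genes). Of 10 fetal and embryonic stage genes HMGA2, NFIA and NFIB fell (3 adjusted over the list alone; camera adjusted p = 0.025, adjusted p = 0.28 with an estimated correlation).

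The other lists did not pass camera between clusters 3 and 0. Of 10 Notch genes 4 rose and 3 fell (5 and 3 adjusted over the list alone; adjusted p = 0.40), with DLL1 up by 4.62 ± 0.44 and NOTCH2 down by 3.53 ± 0.30. Of 13 cell cycle inhibitors 6 rose and 3 fell (6 and 3; 0.27), with CDKN1C at 2.22 ± 0.10 and CDKN1A at 1.66 ± 0.15. Of 19 glycolysis genes 4 rose and 10 fell (4 and 10; 0.14), with the muscle enolase ENO3 up by 3.25 ± 0.14 and ENO1 down by 0.91 ± 0.09. Of 12 imprinted genes 3 rose and 4 fell (3 and 4; 0.39), and of 16 growth factor receptors 2 and 7 (2 and 7; 0.22). Of 13 fusion and adhesion genes 4 rose and 7 fell (4 and 7; 0.40), and of 14 premyogenic factors 5 and 6 (6 and 7; 0.75). Myostatin (MSTN), the secreted inhibitor of muscle growth, rose by 5.00 ± 0.63. Of 17 dissociation stress genes 4 rose and 7 fell (4 and 8; 0.67). Of 52 G2M genes 6 rose and 5 fell (4 and 4; 0.40) and of 38 S phase genes 1 rose and 7 fell (1 and 7; 0.089). The G2M median was -0.07, and 0.01 with 5 genes without UMIs at their bound; the S phase median was -0.53, and -0.19 with 8 such genes at their bound.

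In all, 1664 genes were higher and 1606 lower in cluster 3 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 9654 tested), and 3226 of the 3270 had the same sign in both libraries; with no filter on low counts 1352 were higher and 1938 lower. The count was 2080 of 6581 with separate parts of the UMIs, 1450 with thinned cells and 1993 with DESeq2. Clusters 3 and 2 were compared after these results had been seen, and 814 genes were higher and 730 lower in cluster 3. MYOG and MYOD1 were higher there by 1.56 ± 0.18 and 1.46 ± 0.16, MYH3 by 3.71 ± 0.14, and PAX7 was lower, at -2.83 ± 0.39.

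**Figure D3:**
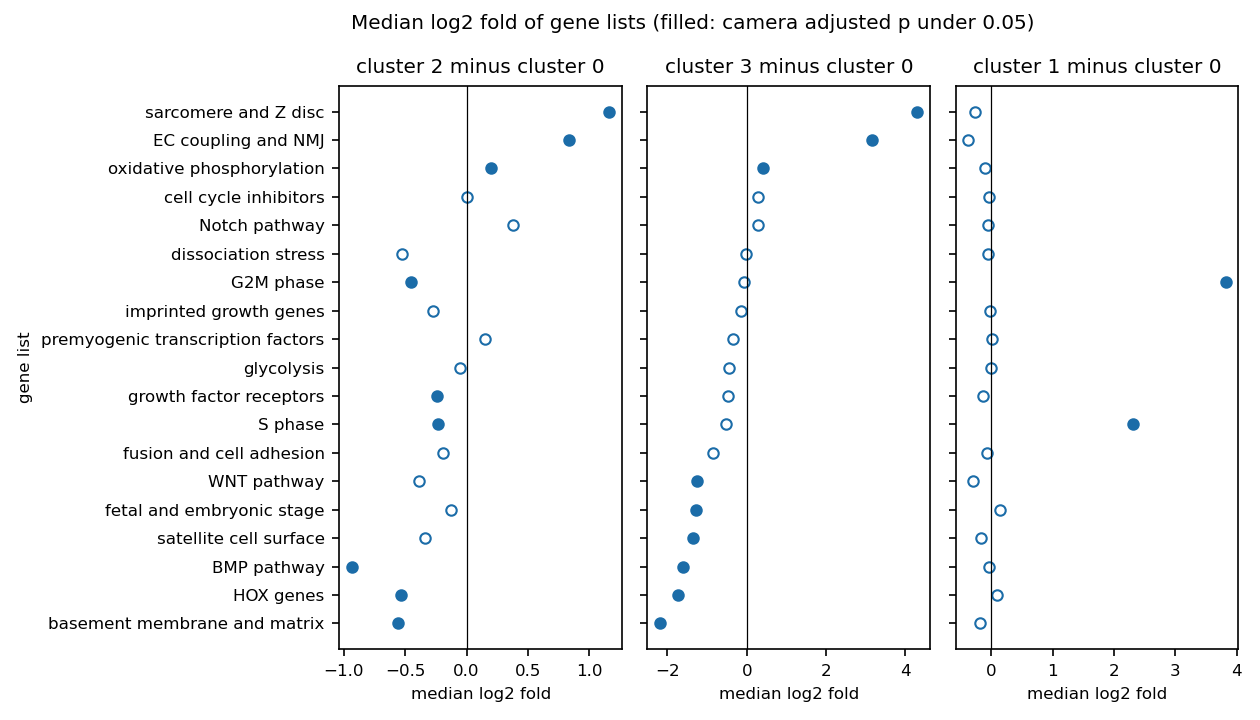
Median log2 fold (horizontal axes) of the measured members of each gene list (vertical axis) in 3 comparisons with cluster 0; filled points passed camera with its preset correlation. Sarcomere and Z disc genes stand at 1.16 in cluster 2 and 4.30 in cluster 3, and the G2M and S phase lists at 3.82 and 2.31 in cluster 1.

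Cluster 1, the cycling-like cells, was compared with cluster 0 to ask whether cells in and out of the cell cycle differed in more than cycle genes. All 10 cycling markers rose, as the cluster's name requires, and 51 of 52 G2M genes and 35 of 38 S phase genes rose (52 and 37 adjusted over the list alone). The G2M list shares TOP2A, CENPF, UBE2C, CDK1 and others with the markers that named the cluster. Its rise is thus no separate support for the name. HJURP, which loads the centromeric histone, rose by 5.89 ± 0.47, and the kinetochore motor CENPE by 4.78 ± 0.30. The medians were 3.82 and 2.31, and both lists passed camera (adjusted p = 3.4e-66 and 5.8e-46) and also with an estimated correlation (adjusted p = 0.023 and 0.0092). Among genes at 50 CPM or more in cluster 1 that are not markers, the largest rises were those of DTL (6.13 ± 0.43), CDCA8 (5.72 ± 0.41) and GTSE1 (5.32 ± 0.33). They were followed by the histone chaperone ASF1B (5.25 ± 0.38), TACC3 (5.16 ± 0.29), PIMREG (5.01 ± 0.32), the ribonucleotide reductase subunit RRM2 (5.00 ± 0.18) and the kinesins KIF20A (4.92 ± 0.30), CENPE and KIF2C (4.74 ± 0.32).

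The regulators themselves did not pass between clusters 1 and 0: PAX7 had a log2 fold of -0.12 ± 0.14, MYF5 -0.46 ± 0.19, MYOD1 0.02 ± 0.16, MYOG 0.46 ± 0.42 and PAX3 0.00 ± 0.39 (edgeR, adjusted p = 0.68, 0.099, 0.97, 0.59 and 0.999). The largest falls by the same limit were smaller than the rises. They were those of the cell cycle inhibitor CDKN1A (-1.56 ± 0.19), OGN (-1.48 ± 0.14), the MAX partner MXD4 (-1.45 ± 0.22) and MXRA8 (-1.13 ± 0.16). Next came the activin-binding protein follistatin (FST, -1.07 ± 0.11), SERPINF1 (-1.05 ± 0.21), PLTP (-1.04 ± 0.23), the imprinted DLK1 (-0.97 ± 0.14), the p53 target ZMAT3 (-0.89 ± 0.18) and KLHL41 (-0.86 ± 0.17). SERPINF1 and PLTP did not pass with separate parts of the UMIs by edgeR (adjusted p = 0.092 and 0.062). Of the CDKN1A UMIs in cluster 0 (418 in replicate 1 and 219 in replicate 2), 183 lay in the 6 cells named above. In these cells CDKN1A stood at 4003 and 827 CPM in replicates 1 and 2, against 68.0 in the rest of the cluster. The size of the CDKN1A fall thus rests in part on these cells, and its rank is not read as a property of cycling cells.

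Marker sets other than cycling moved in part: of 5 measured neuron markers 3 fell (GAP43, NEFL and NEFM), of 8 mesenchymal markers 3 (POSTN, COL3A1 and COL1A2) and of 5 smooth muscle or pericyte markers 2 (CNN1 and NOTCH3; 3, 3 and 3 adjusted over each list alone). In cluster 0 POSTN came mostly from the 52 and 6 cells named above, so its fall is not read as a change in cycling cells. Of 9 progenitor markers CDH15 fell (3 alone), of 10 committed myoblast markers HES6 rose (1 alone), and no myocyte marker passed (3 fell alone). Of the pathway lists no other passed camera in cluster 1. Counts of rises and falls were 0 and 2 of 22 basement membrane genes (1 and 3 adjusted over the list alone; adjusted p = 0.13), 0 and 2 of 23 sarcomere genes (0 and 2; 0.098) and 0 and 1 of 14 excitation contraction coupling genes (0 and 1; 0.11). They were 0 and 2 of 13 WNT genes (0 and 2; 0.21), 0 and 1 of 9 BMP genes (0 and 1; 0.82) and 1 and 1 of 10 Notch genes (2 and 1; 0.82). They were 1 and 3 of 13 cell cycle inhibitors (1 and 4; 0.60), 2 and 3 of 17 dissociation stress genes (2 and 3; 0.82) and 0 and 2 of 19 glycolysis genes (0 and 2; 0.60), followed by 2 and 4 of 36 oxidative phosphorylation genes (2 and 4; 0.51), 0 and 3 of 12 imprinted genes (0 and 3; 0.60). The remaining counts were 1 and 1 of 14 premyogenic factors (1 and 1; 0.82) and 1 and 0 of 10 fetal and embryonic stage genes (2 and 0; 0.60), the rise being that of HMGA2 at 0.56 ± 0.15. No member of the HOX (14 genes; 0.84), satellite cell surface (10; 0.51), growth factor receptor (16; 0.44) or fusion and adhesion (13; 0.60) lists passed over all genes or alone. The Notch median of -0.05 stood against a mean of 0.20, and the premyogenic median of 0.01 against a mean of -0.01. GADD45G rose by 1.74 ± 0.46 in the fit but had a log2 fold of -0.53 in replicate 2 alone.

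In all, 723 genes were higher and 381 lower in cluster 1 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 9654 tested), 403 and 61 of them by over 2-fold, and 1100 of the 1104 had the same sign in both libraries. The count was 648 of 6581 with separate parts of the UMIs, 492 with thinned cells, 443 without the library block (408 higher and 35 lower) and 384 with DESeq2.

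The last question was how closely the 2 experiments matched. Summed over all cells, log2 CPM of the 9654 tested genes differed between libraries with an SD of 0.33, and 67 genes (0.694%) differed by over 2-fold; Pearson's r across genes, which are not independent replicates, was 0.978. Within cluster 0 the SD was 0.38 and 157 genes (1.63%) differed by over 2-fold. The 5 widest gaps among abundant genes, picked after their values were seen, were all higher in replicate 2. The immediate early gene EGR1 was at 4.49 CPM in replicate 1 and 405 in replicate 2, CTGF at 18.8 and 118, CYR61 at 35.7 and 202, JUNB at 38.0 and 126, and IER2 at 45.9 and 129.8. Of the 22 dissociation stress genes in the matrix 10 were over 2-fold higher in replicate 2 and 0 in replicate 1, and FOS stood at 1.07 and 37.9 CPM. The mitochondrial complex genes NDUFB2 (138 and 52.1 CPM) and NDUFB6 (115 and 45.8 CPM) were higher in replicate 1.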

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

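The comparison of clusters 3 and 2, the fits without subgroups of cluster 0 and the tests of genes highest in cluster 2, of the subgroup and of the background level were chosen after the data were seen. Counts of genes past the threshold fell with the test, the depth and the count split: for clusters 2, 3 and 1 against 0, DESeq2 gave 584, 1993 and 384 in place of 1388, 3270 and 1104, thinned cells 615, 1450 and 492 and the count split 835, 2080 and 648 (both with fewer genes tested). Without the library block the counts were 694, 2498 and 443, since the spread between the paired libraries then entered the error. For clusters 3 and 2 the count of 1544 became 975 without the block, 731 in the count split, 584 with thinned cells and 811 with DESeq2. RLE factors, no filter, no doublets and the other fits kept these counts within 1.5 times. The balance of calls did not hold: cluster 2 went from 726 higher and 662 lower to 678 and 741 with RLE, 524 and 782 with no filter and 669 and 680 without the subgroups, cluster 3 from 1664 and 1606 to 1352 and 1938 with no filter and 1241 and 1257 without the block, and clusters 3 and 2 from 814 and 730 to 657 and 666 with no filter. The PAX7 and MYF5 odds ratios of 1.94 and 1.89 were 1.57 and 1.42 at 5000 UMIs, with intervals that take in 1, and 3.37 and 2.19 unthinned. Of 19 lists, 9 passed in clusters 2 and 3 and 0 did with an estimated correlation; fry gave 14 in cluster 3 and 7 in cluster 2, where it lost G2M (0.141), S phase (0.0604) and oxidative phosphorylation (0.0700). Rebuilt clusters at resolution 0.3 gave shares of 65.4%, 17.2% and 9.08% for clusters 0, 1 and 2, and at 1.0 63.4% for cluster 0 and 9.34% for cluster 2, with 93.2% and 93.0% of cells in the same class; filters on low totals removed no cell. The share with a PAX7 UMI was 48.1% unthinned and 39.2% at 5000 UMIs, so it depended on depth. Genes over 2-fold apart between libraries were 1.86% over all cells with no filter and 0.667% at 50 CPM or more. In cluster 0 they were 4.87% and 0.871%, and the cause was not tested. Of 228 named results past the threshold, 138 were neither lost nor reversed under the alternatives that tested them; of 234 pairs of gene and comparison, 196 were tested with thinned cells and 209 in the count split. In cluster 2, FOS had a log2 fold of 0.19 with DESeq2 and between -3.12 and 1.08 in single libraries, and HSPA1A -1.27 in the count split and between -0.20 and 1.34. In cluster 1, DLL1 had a log2 fold of -0.0790 in the count split and GADD45G -0.39, and GADD45G lay between -0.53 and 2.22 in single libraries; the cause was not tested. Fits with 1 library leave no residual degrees of freedom, so counts without a replicate were not run, nor was any comparison of a non-myogenic class.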

Other observations

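The counts of genes highest in cluster 2, of the subgroup of cluster 0 and of the 6-cell group, and the tests of mixed cells by random parts of a cluster and of free RNA, were chosen after the results were seen. HOX genes, which mark position along the body axis, were low in the most posterior groups. Of 32 HOX genes in the matrix 14 reached 10 CPM over all cells. HOXC6 (63.5 ± 1.47 CPM, n = 2) and HOXD9 (63.1 ± 8.92) were the highest, HOXA10 stood at 9.05 ± 2.90, and HOXA13 at 1.15 ± 0.796. By the mean of both libraries paralog group 9 was the last with a member at 10 CPM or more, but in replicate 1 HOXA10 reached 11.1 CPM.

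Rebuilt clusters set apart 52 cells of cluster 0, 26 from each library and none called a doublet. Against cluster 0 without these and 6 further cells, edgeR gave 133 genes higher and 246 lower of 9221, and 72 of the lower ones were ribosomal protein genes with a median of -0.36. The matricellular gene POSTN was higher by 7.50 ± 0.36 on the log2 scale, the transcription factor ZIC1 by 2.71 ± 0.22, CD24 by 2.61 ± 0.28 and PAX3 by 2.06 ± 0.49, while IGFBP3 was lower at -5.29 ± 0.52 and PAX7 had -0.59 ± 0.24 and did not pass (adjusted p = 0.20). A group rebuilt from a part of the UMIs held 148 cells, 46 of them from the 52, and 37 genes were higher and 39 lower in the other part. It was the rebuilt group with the largest share of the 52 cells. Its comparison cells left out the 52 and 6 cells, which had been set apart with all UMIs. The test in the other part was therefore not independent of that choice. There POSTN was higher by 6.14, ZIC1 by 1.97 and CD24 by 3.09, IGFBP3 was lower by only 1.04, and PAX3 was not tested. MYOD1 was higher by 0.94 ± 0.25 with edgeR (adjusted p = 0.014) but did not pass there (0.68, adjusted p = 0.25), nor did any of the 72 ribosomal protein genes. The 6 further cells, 3 per library, had the highest POSTN of these groups, at 2431 and 4261 CPM, IGFBP7 at 4544 and 1448 CPM and KRT18 at 270.2 and 3102 CPM. They held 1 UMI each of PAX7 and MYF5 and 0 of MYOD1, MYOG and PAX3. PAX7 stood at 136 CPM in the rest of cluster 0, but 6 cells are too few for a test.

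In cluster 2, 53 genes were higher than in both clusters 0 and 3, among them the carboxypeptidase M gene (1.92 over cluster 0), EDN3 (1.71), IL4R (1.52) and NGFR (1.46). A mixture of cells or doublets typical of clusters 0 and 3 puts every gene between the levels of those clusters. Yet 12 genes, these 4 included, passed both tests in both assignments of a random part of the cluster's cells to each comparison, 11 of them with the same directions in each library (not HSPA1A). In the count split 24 genes passed both tests, 21 of them among the 53 (39.6%). Fewer than 10% was set as the mark of clusters drawn from the tested counts. The 53 were picked with all UMIs, the tested part included, and the same sums of cluster 2 entered both tests. That share is therefore not an independent check. The random parts argue against a mixture of cells typical of clusters 0 and 3 as the whole cause. A distinct subset of cluster 0 counted in cluster 2 would be in every random part, so that case stays open. The count split cannot decide about clusters drawn from the tested counts, since its share is not independent, and no conclusion is drawn from it. A mixture and such clusters acting together were not tested. Leaving out called doublets kept 96.2%, but with 4 of 191 cells of cluster 2 called it decides nothing, so doublets of other kinds stay open, and no biological explanation was tested.

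Cluster 3 held 10 PAX7 UMIs, 7.19% of the level in cluster 0 (counting interval 3.44 to 13.3). Free RNA may account for some or all of them: the 10 genes of at least 200 CPM with the lowest relative level in cluster 3 stood at a pooled 3.51% (2.72 to 4.46), just inside the PAX7 interval. That margin is thin, and it depends on the level a gene needs: a version at 50 CPM, run after the first had been seen, gave 3.15% (1.99 to 4.73), just outside, with overlapping intervals. The genes were picked in 1 part of the UMIs and measured in the other, where the members at 200 CPM differed. MATN2 had 2 UMIs in cluster 3 against 718 in cluster 0 and OGN 1 against 801, but MYH9 had 12 against 902. Genes that cluster 3 itself expresses would raise the pool above free RNA, so the test cannot show that free RNA gave all 10 UMIs. Cells of cluster 0, or doublets with them, counted in cluster 3 are also possible, since the 8 cells of cluster 3 with a PAX7 UMI had 2.29 times the mesenchymal marker share of the other 112 (1.13 to 3.77; one-sided permutation test, p = 0.017), and 2 of the 8 were called doublets. Both explanations stay open, and no biological one was tested.

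Mesenchymal marker UMIs were found throughout cluster 0. Separate mesenchymal cells without PAX7, if they held more of these UMIs in sum, would give fewer PAX7 cells where the UMIs are most frequent. The share with a PAX7 UMI was 25.7% in the third of cells with the most and 28.9% in the third with the fewest, a ratio of 0.890 (0.680 to 1.17). The libraries differed here, at 0.583 in replicate 1 and 1.13 in replicate 2. Free RNA in every droplet is argued against by the level in cluster 3, 9.68% of that in cluster 0. PAX7 cells that also express matrix genes may make up much of cluster 0, a hypothesis found and tested on the same data. Small groups of cells without PAX7 stay open.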
